A study of Mus musculus with 4 samples.

How the data were processed

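RNA of sorted Dll1-mCherry-positive mouse mammary tumor cells was measured by poly(A) RNA sequencing in 2 unirradiated and 2 irradiated libraries. Per the labels' protocols, libraries were made with a non-directional kit after oligo(dT) selection and random priming, so strand is not kept. The authors deposited raw counts per gene, with gene names, positions and gene lengths in bases as further columns. Per the submitters' processing notes STAR 2.5, HTSeq 0.6.1, DESeq2 (no version) and the mm10 build were used; the annotation release and the counting options are not given in the sources used here. For irradiated 2 the deposited count table holds all 4 libraries, and its other 3 columns were identical to the single tables of those libraries at all 54532 genes. Of the 54532 gene IDs 54495 were found in GENCODE M21 (GRCm38), of which 53585 (98.3%) have the same chromosome, start and end, so positions are given as in the files. The summed counts were 20817997, 16811888, 19931303 and 18903631 in unirradiated 1, unirradiated 2, irradiated 1 and irradiated 2.

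Groups and replicate numbers come from the sample labels. Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 15993, libraries were scaled by TMM, and group differences were tested with the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. CPM values are TMM-normalized, and log2 CPM used a prior count of 2. SDs are over 2 libraries. The log2 difference of an irradiated library is its log2 CPM minus the mean of the unirradiated libraries. An exact permutation test of 2 against 2 libraries cannot give a p below 0.333, so tests of single genes rest on the genome-wide models.

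The comparison, its test, the alternatives, the gene lists and the rule for naming genes were set before the data were examined. The 38 lists cover p53 targets, double-strand break repair, mitosis, DNA replication, interferon-stimulated genes, MHC class I presentation, NF-kB targets, cytokines and chemokines, senescence, the Notch, Wnt and TGF-beta and BMP pathways, mesenchymal transition, epithelial adhesion, basal and luminal mammary epithelium, milk and secretory products, stem and tumor-initiating cells, keratinization, hypoxia and glycolysis, oxidative phosphorylation, the unfolded protein and integrated stress response, the antioxidant response, anti-apoptotic and pro-apoptotic genes, cholesterol synthesis, immediate early and dissociation genes, cytosolic ribosomal proteins, mitochondrial genome transcripts, and markers of fibroblasts, pericytes, endothelium, macrophages, neutrophils, lymphocytes, red cells, adipocytes and skeletal muscle. Lists with at least 5 tested members were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry were alternatives. Some genes are on more than 1 list. A member is said to lie above or below when both irradiated libraries lie on that side of both unirradiated ones. How often unchanged genes would do so at the unequal spread of the groups was not estimated, so such counts are descriptive. Dll1, Cdkn1a and Mdm2 are always named. Where no gene passes in a direction, the rule names the 8 with the smallest p that have an average log2 CPM of at least 1, both irradiated libraries on 1 side of both unirradiated ones and a symbol that is not a predicted one, and for each list with no member past the threshold the 2 with the smallest p. All are given as values only, and 1 gene under this rule is not reported here. Hey1, Ttk, Hmmr, Lcn2, Csn3, Vim, Vegfa and Fos were added after their values were seen.

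The alternatives were DESeq2 size factors, upper-quartile scaling and library size alone in edgeR, no filter, a stricter filter (CPM above 1 in 2 libraries), the replicate number as a block, each library left out in turn, an adjusted p threshold of 0.1, an added log2 fold threshold of 1, limma-voom and DESeq2 1.42.0. A robust quasi-likelihood fit was added after seeing the data. The fits of each irradiated library against the unirradiated pair estimate the spread from that pair alone. Unchanged libraries for those fits were drawn 20 times from the unirradiated means and their trended dispersion, and 20 times with the irradiated libraries given the trended dispersion of the irradiated pair, a step added after seeing the data.

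The steps were tested on simulated data with the real means and library sizes, dispersions estimated from the data and 200 changed genes. In simulations of 2 against 2 libraries each gene had the same dispersion in both groups. The real groups differed in spread, so the rates below may not hold for them. In 5 simulations of 2 against 2 libraries edgeR, run on a mean of 16215 genes, recovered 36.8% of genes changed 2-fold and 83.6% of those changed 4-fold, with a mean of 15.2 unchanged genes called. DESeq2, run on 27538 genes, recovered 59.2% and 92.2% with 58 unchanged genes called, and edgeR without a filter, run on 26140 genes, recovered 57.2% and 91.2% with 89.6. For 1 irradiated against 2 unirradiated libraries, where all libraries were drawn with the spread of the unirradiated pair, edgeR recovered 95.4% and 99.8% over 16824 genes with 18.8 unchanged genes called. With the interferon-stimulated list raised 1.5-fold and genes drawn independently, camera called it in 10 of 10 simulations and called 0 of 369 unchanged lists. In the real data the estimated correlation ran from -0.0393 (stem and tumor-initiating cell list) to 0.996 (fibroblast markers). The simulated rate of false calls does not carry over to lists whose genes vary together.

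Exons of 26 of the 89 named genes overlap those of another annotated gene, and in 7 the overlap exceeds 10% of the exon bases, which the counts cannot resolve without strand.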

Results

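Dll1-positive tumor cells of mouse mammary tumors driven by the polyoma middle T antigen under the MMTV promoter were compared between tumors left unirradiated and tumors given targeted radiation on day 30. Dll1, a ligand of Notch receptors, was read through an mCherry reporter. Digested tumors were first sorted with antibodies against CD45, CD31 and TER119, which mark blood cells, endothelium and red cells, to enrich tumor cells, and the mCherry-positive cells were then collected. Poly(A) RNA of 4 libraries was sequenced, 2 unirradiated and 2 irradiated. The summed counts were 20817997 and 16811888 in the unirradiated libraries and 19931303 and 18903631 in the irradiated ones. The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

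The unirradiated libraries lay close together and the irradiated ones did not. Across genes, the biological coefficient of variation was 5.93% between the unirradiated libraries and 39.6% between the irradiated ones, and 2463 genes differed over 2-fold between irradiated 1 and irradiated 2 against 522 between the unirradiated pair. Irradiated 2 stood apart on the first principal component of log2 CPM, which held 65.3% of the variance, and irradiated 1 on the second, with 27.6%. The chi-square between the unirradiated libraries was 5.32 per gene over 12075 genes, above counting noise, which library preparation alone can exceed. Codes in front of the sample titles split exactly as the treatment does, so any processing step tied to them cannot be told apart from radiation.

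The comparison asked how gene expression of Dll1-positive tumor cells differed after radiation. Plaur and Tnc were among the genes with the smallest p on the higher side. Plaur, the urokinase receptor gene, was at 45.9 ± 3.30 CPM in the irradiated libraries against 22.3 ± 0.506 CPM in the unirradiated ones (SD, n = 2 each). Tnc, which encodes the matrix protein tenascin C, was at 66.1 ± 14.1 CPM against 25.0 ± 0.367 CPM. On the lower side, the calcium pump gene Atp2a3 was at 381 ± 21.5 CPM against 729 ± 14 CPM, and the tight junction gene Cldn2 at 37.1 ± 4.34 CPM against 77.0 ± 1.66 CPM. None of these differences passed the test over all genes: the edgeR quasi-likelihood test called 0 of 15993 genes higher and 0 lower, with a smallest adjusted p of 0.489.

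At an unadjusted p under 0.05 the edgeR test held 1480 genes, 1090 higher and 390 lower. If all libraries varied alike, chance alone would give 800. DESeq2 called 450 genes higher and 50 lower, and limma-voom called 0 each way. Without irradiated 1 edgeR called 2713 genes higher and 1354 lower, and without irradiated 2 it called 2022 and 2355, in fits that assume the lone irradiated library to vary like the unirradiated pair. Unchanged libraries simulated with the spread of the irradiated pair gave a mean of 3307 genes higher and 3348 lower in such a fit for irradiated 1, so these counts do not by themselves show a change. The spread of the irradiated pair includes any real difference between those libraries, so the simulation cannot exclude a change either. Both irradiated libraries lay above both unirradiated ones in 3251 genes (20.3%) and below both in 3204 (20.03%). Chance gives 16.7% each way only if all 4 libraries vary alike. The irradiated pair varied more, at 39.6% against 5.93%, which raises that share for unchanged genes. No excess over chance can be read from these counts.

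Others on the higher side included Gbp9, a guanylate-binding protein gene of the interferon response, at 32.9 ± 1.68 CPM against 10.1 ± 0.542 CPM. The glutamine transporter gene Slc1a5 was at 77.3 ± 0.793 CPM against 36.7 ± 1.41 CPM. Slfn4, a Schlafen family gene, was at 18.7 ± 2.67 CPM against 4.13 ± 0.0827 CPM, and Cyp1b1, a cytochrome P450 gene, was at 20.97 ± 4.02 CPM against 5.48 ± 0.261 CPM. The acidic chitinase gene Chia1 was nearly silent without radiation, at 0.220 ± 0.106 CPM. It was at 8.22 CPM in irradiated 1 and 25.2 CPM in irradiated 2. Chia1 is also on the list of salivary-type secretory transcripts given below, whose source is not known. In the edgeR fit the log2 fold changes of these genes ran from 1.04 for Plaur (SE 0.13) to 6.24 for Chia1 (SE 0.80). Gbp9 and Slfn4 belong to families of near-identical copies, so reads shared between members make their values uncertain.

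Mfsd4a and Clic6 were among the 8 genes with the smallest p on the lower side, none of which passed edgeR. Mfsd4a, a membrane transporter gene, was at 49.9 ± 6.27 CPM against 116 ± 6.18 CPM, and Clic6, a chloride channel family gene, was at 316 ± 7.58 CPM against 549 ± 6.86 CPM. The amino acid transporter gene Slc6a14 was at 15.9 ± 1.36 CPM against 33.2 ± 1.27 CPM. Smoc1, which encodes a calcium-binding matrix protein, was at 99.9 ± 0.933 CPM against 173 ± 4.24 CPM, Sidt1 at 52.98 ± 1.34 CPM against 92.1 ± 4.35 CPM, and the kinase gene Stk26 at 50.5 ± 3.00 CPM against 85.4 ± 5.15 CPM. By DESeq2 each gene given above for its smallest p passed an adjusted p of 0.05, from 3.94e-12 for Chia1 to 0.00144 for Stk26, while by edgeR none did. Their log2 differences from the unirradiated mean were of like size in both irradiated libraries, for example -0.80 and -0.78 for Smoc1. Chia1 was the exception, with 4.72 and 6.33. The naming rule favors genes that are alike in both irradiated libraries, so this likeness is no separate evidence of a change.

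In mm10, Plaur (ENSMUSG00000046223) lies on chromosome 7 from 24462484 to 24475968, Tnc (ENSMUSG00000028364) on chromosome 4 from 63959785 to 64047015, and Atp2a3 (ENSMUSG00000020788) on chromosome 11 from 72961169 to 72993044. Dll1 (ENSMUSG00000014773) lies on chromosome 17 from 15367354 to 15376872, and its exons share 20.5% of their bases with those of the antisense gene A930024N18Rik. Mfsd4a exons share 22.8% with the antisense gene Gm26892, which had no counts. The library kit does not keep strand, so reads in such shared exons cannot be assigned to a gene.

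**Figure D1:**
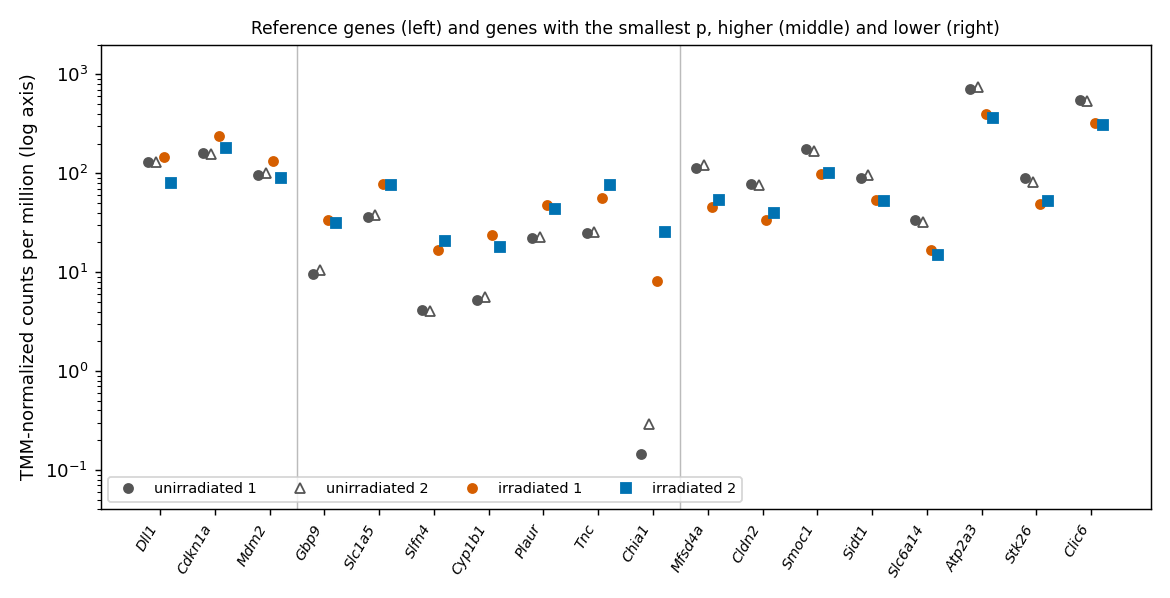
TMM-normalized CPM, on a log axis, of Dll1, Cdkn1a and Mdm2 and of genes with the smallest p in each direction. Each point is 1 library. Tnc was at 56.2 and 76.1 CPM in the irradiated libraries against 24.8 and 25.3 CPM in the unirradiated ones, and Dll1 was lowest in irradiated 2.

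Dll1 itself, whose reporter defined the sort, was at 130 and 129 CPM in the unirradiated libraries, 146 CPM in irradiated 1 and 80.2 CPM in irradiated 2 (log2 fold change -0.20, SE 0.29). Left to irradiated 1 alone against the unirradiated pair, its log2 fold change was 0.16. The p53 targets Cdkn1a, a cell cycle inhibitor gene, and Mdm2, which encodes the ligase that degrades p53, were highest in irradiated 1. Cdkn1a was at 237 CPM there and 182 CPM in irradiated 2 against 161 and 157 CPM, and Mdm2 at 133 and 90.5 CPM against 95.8 and 101 CPM. Without irradiated 1 the log2 fold change of Mdm2 was -0.14.

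No clear shift of the DNA damage and cell cycle lists was measured. Of 27 p53 targets, 9 lay above both unirradiated libraries in both irradiated ones and 6 below, 0 passed over all genes and 0 when adjusted over the list alone, and the camera adjusted p was 0.483. Pmaip1, a death-promoting BH3-only gene, was at 13.0 and 26.1 CPM in the irradiated libraries against 5.39 and 4.42 CPM, and Plk2 at 582 and 475 CPM against 374 and 378 CPM. Of 30 double-strand break repair genes 8 lay above and 3 below (adjusted p = 0.483); H2afx, the histone variant of DNA breaks, was at 32.9 and 35.7 CPM against 26.4 and 25.4 CPM, and Rad54l at 9.63 and 6.72 CPM against 4.96 and 5.54 CPM. Among 25 mitosis genes 4 lay above and 0 below (adjusted p = 0.51), with Kif23 at 17.2 and 14.5 CPM against 10.1 and 11.5 CPM and Bub1b at 25.6 and 27.2 CPM against 19.8 and 21.1 CPM. Among 28 DNA replication genes 7 lay above and 1 below (adjusted p = 0.141), with Pole at 11.9 and 10.2 CPM against 7.03 and 7.90 CPM and Mcm3 at 29.7 and 39.2 CPM against 26.1 CPM in each unirradiated library. In none of these lists did a member pass when adjusted over the list alone. The irradiated libraries differed in direction: the median was -0.16 in irradiated 1 and 0.28 in irradiated 2 for mitosis and -0.0743 and 0.26 for replication. The spindle kinase gene Ttk was at 2.37 and 6.34 CPM against 5.10 and 5.37 CPM and Hmmr at 8.07 and 15.6 CPM against 12.1 and 15.4 CPM. Without irradiated 1 the mitosis and replication lists passed upward by camera, at adjusted p = 0.0138 and 0.00951, and without irradiated 2 both pointed down without passing, at 0.084 and 0.37.

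Of 37 gene lists with at least 5 tested members, 18 passed the camera test with its preset correlation, 16 upward and 2 downward. No list held with the correlation estimated from the 4 libraries, where the smallest adjusted p was 0.681, and the senescence-associated list alone had an unadjusted p under 0.05 (0.0359). The directional fry test called 1 list, the NF-kB targets. The mixed fry test, which counts changes either way, also passed other lists. Among them were the p53 targets (mixed fry adjusted p = 0.0406) and the luminal and milk lists (0.0154 each). Others did not pass it, such as mitosis (0.68) and macrophage markers (0.232). Over all genes 0 members of any list passed edgeR.

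Part of the interferon-stimulated and antigen presentation genes lay higher. Of 30 interferon-stimulated genes 16 lay above both unirradiated libraries in both irradiated ones and 1 below, and the list passed upward (camera adjusted p = 0.000129, and adjusted p = 0.681 with an estimated correlation). Its median log2 difference was 0.28 in irradiated 1 and 0.14 in irradiated 2, and without irradiated 1 the adjusted p was 0.125. Oasl1, an oligoadenylate synthetase-like gene, was at 68.1 and 56.6 CPM against 40.8 and 39.0 CPM, and Rsad2, which encodes the antiviral protein viperin, at 111 and 95.9 CPM against 76.8 and 72.2 CPM. Of 16 genes of MHC class I presentation 7 lay above and 1 below, 4 passed when adjusted over the list alone, and the list passed at adjusted p = 0.0145 (adjusted p = 0.681 with an estimated correlation). Tap1, the peptide transporter gene, was at 148 and 145 CPM against 109 and 106 CPM, and the immunoproteasome gene Psmb8 at 109 CPM in each irradiated library against 81.7 and 81.2 CPM. Macrophage and lymphocyte markers, from cells that also carry these transcripts, were higher in both irradiated libraries, with medians of 2.42 and 5.62 and of 1.93 and 4.48. The class I call was lost without any 1 of the 4 libraries, with adjusted p from 0.0976 without unirradiated 1 to 0.265 without unirradiated 2.

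Many genes of inflammatory and secreted factors lay higher too. Of 32 NF-kB targets 15 lay above and 5 below, 3 passed when adjusted over the list alone, and the list passed at adjusted p = 0.00515 (adjusted p = 0.681 with an estimated correlation), with medians of 0.18 in irradiated 1 and 0.17 in irradiated 2. The call was lost without irradiated 2 (adjusted p = 0.0543). Ccl2, a monocyte-attracting chemokine gene, was at 25.3 and 38.3 CPM against 13.4 and 10.498 CPM, and Ptgs2, the inducible cyclooxygenase gene, at 56.9 and 43.6 CPM against 26.8 and 28.3 CPM. Lcn2, a more abundant member of the list, was lower, at 3945 and 3513 CPM against 5009 and 4498 CPM. Of 35 cytokine and chemokine ligands 23 lay above and 4 below (adjusted p = 2.37e-05, and adjusted p = 0.681 with an estimated correlation), with a median log2 difference of 0.43 in irradiated 1 and 1.39 in irradiated 2, the library with high markers of other cell types, and 0 passed when adjusted over the list alone. Cxcl9, a chemokine gene induced by interferon gamma, was at 3.08 and 7.09 CPM against 0.481 and 0.649 CPM. Of 21 senescence-associated genes 16 lay above and 2 below, 5 passed when adjusted over the list alone, and the list passed at adjusted p = 1.2e-07 (adjusted p = 0.681 with an estimated correlation). Its medians were 0.54 in irradiated 1 and 1.56 in irradiated 2, again the library with high markers of other cell types. Its members Igfbp4, Igfbp7 and Mmp3 are also among the further abundant transcripts of other cells given below. Plaur was among the members with the smallest p.

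Developmental signaling lists differed by small amounts. Of 32 Wnt pathway genes 15 lay above and 3 below (adjusted p = 0.00897, and adjusted p = 0.681 with an estimated correlation), and 0 passed when adjusted over the list alone. The feedback target Axin2 was at 8.93 and 10.502 CPM against 3.42 and 4.13 CPM, and the secreted inhibitor gene Wif1 at 6.56 and 9.54 CPM against 22.0 and 20.5 CPM. The Wnt call was lost without unirradiated 1 (adjusted p = 0.138), irradiated 1 (0.0945) or irradiated 2 (0.0691). Of 31 TGF-beta and BMP pathway genes 13 lay above and 3 below, and 2 passed when adjusted over the list alone, among them Inhba, the activin subunit gene, at 8.78 and 6.77 CPM against 2.502 and 1.89 CPM. That list passed at adjusted p = 0.0384 (adjusted p = 0.681 with an estimated correlation), and without any 1 library its adjusted p was between 0.0696 without unirradiated 2 and 0.186 without unirradiated 1. Of 31 Notch pathway genes 10 lay above and 5 below (adjusted p = 0.202), 0 passing when adjusted over the list alone, with the ligand gene Jag1 at 29.4 and 37.7 CPM against 17.4 and 17.5 CPM and Notch4, which endothelium also expresses, at 19.7 and 39.2 CPM against 9.96 and 11.97 CPM. The Wnt, TGF-beta and Notch values came with high markers of other cell types, the endothelial ones at medians of 0.69 in irradiated 1 and 4.99 in irradiated 2. The Notch target Hey1 was at 224 and 187 CPM against 263 and 260 CPM.

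Luminal and secretory identity genes lay on both sides, and neither list passed by camera. Of 19 milk and secretory genes 5 lay above and 9 below, and 4 passed when adjusted over the list alone, while the list as a whole did not pass (adjusted p = 0.343). Casein gene Csn2 was at 14.3 and 15.7 CPM against 4.81 and 3.48 CPM, whereas Csn3, another casein gene, was at 4895 and 5194 CPM against 7108 and 6208 CPM and the butyrophilin gene Btn1a1 at 60.1 and 66.0 CPM against 98.5 and 101 CPM. Of 19 luminal genes 3 lay above and 8 below (adjusted p = 0.343), and 2 passed when adjusted over the list alone. The transcription factor gene Tbx3 was at 19.6 and 16.5 CPM against 7.27 and 7.08 CPM, and Spdef, a regulator of secretory cells, at 23.3 and 28.9 CPM against 42.6 and 44.4 CPM. Of 20 basal genes 4 lay above and 6 below (adjusted p = 0.611), with the oxytocin receptor gene Oxtr at 15.5 and 14.9 CPM against 24.7 and 25.2 CPM and Nrg1 at 14.4 and 11.6 CPM against 19.2 and 19.6 CPM. The basal list had a positive median log2 fold change of 0.0914 and mean of 0.12 but a downward test direction, while the luminal (median -0.0877, mean 0.0606) and milk (-0.18 and 0.16) lists had a negative median, a positive mean and a downward test direction. Among 22 stem and tumor-initiating cell genes 7 lay above and 6 below (adjusted p = 0.738), with Abcc1 at 36.8 and 38.5 CPM against 25.8 and 29.7 CPM and Kit at 293 and 251 CPM against 341 and 376 CPM. Of 16 keratinization genes 4 lay above and 3 below (adjusted p = 0.556), with Klk10 at 12.9 and 9.38 CPM against 5.87 and 5.31 CPM and Krt6a at 13.5 and 9.97 CPM against 7.17 and 5.01 CPM. In the basal, stem cell and keratinization lists 0 members passed when adjusted over the list alone.

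The epithelial adhesion list passed downward and the mesenchymal list upward. Of 28 epithelial adhesion genes 2 lay above and 12 below, with Grhl1 at 88.8 and 84.4 CPM against 104 and 111 CPM and Krt7 at 292 and 257 CPM against 219 and 212 CPM, and 0 passed when adjusted over the list alone. Its adjusted p was 0.00764 by camera (adjusted p = 0.799 with an estimated correlation). The medians were -0.01 in irradiated 1 and -0.29 in irradiated 2, and the call was lost without irradiated 2 (adjusted p = 0.784) or unirradiated 1 (0.0731). Of 18 mesenchymal transition genes 13 lay above and 0 below, and 2 passed when adjusted over the list alone, Tnc and the fibronectin receptor gene Itga5, at 35.2 and 72.7 CPM against 12.3 and 13.8 CPM. The list passed at adjusted p = 1.69e-06 (adjusted p = 0.696 with an estimated correlation), with medians of 0.28 in irradiated 1 and 2.25 in irradiated 2. Vim, which fibroblasts also express, was at 175 CPM in irradiated 1 and 729 CPM in irradiated 2 against 162 and 149 CPM. The list's size in irradiated 2 came with high markers of other cell types in that library.

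Markers of cell types that the sort should remove were far higher in irradiated 2 and moderately higher in irradiated 1. Of 20 macrophage markers 19 lay above both unirradiated libraries in both irradiated ones, and 19 passed when adjusted over the list alone (camera adjusted p = 6.52e-11, and adjusted p = 0.681 with an estimated correlation). Their median log2 difference was 2.42 in irradiated 1 and 5.62 in irradiated 2. The complement gene C1qa was at 1.83 and 1.18 CPM without radiation, 14.6 CPM in irradiated 1 and 123 CPM in irradiated 2, and Cd68 at 10.49 and 10.3 CPM, 18.1 CPM and 27.8 CPM. Of 14 lymphocyte markers 12 lay above and 12 passed when adjusted over the list alone (adjusted p = 8.29e-08, and adjusted p = 0.681 with an estimated correlation), with medians of 1.93 and 4.48. The immunoglobulin gene Igkc was at 9.28 and 44.1 CPM against 0.722 and 1.30 CPM, and the B cell gene Ms4a1 at 4.24 and 11.1 CPM against 0.818 and 0.177 CPM. Of 6 neutrophil markers 4 lay above and 1, Csf3r, passed when adjusted over the list alone (adjusted p = 0.00583, and adjusted p = 0.704 with an estimated correlation). Csf3r was at 2.12 and 15.2 CPM against 0.337 and 0.295 CPM and S100a9 at 2.93 and 37.3 CPM against 0.722 and 2.06 CPM. Without irradiated 2 the neutrophil list had an adjusted p of 0.0919.

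Stromal and vascular markers were highest in irradiated 2. Of 19 endothelial markers 14 lay above both unirradiated libraries in both irradiated ones (adjusted p = 6.48e-06, and adjusted p = 0.71 with an estimated correlation), with medians of 0.69 in irradiated 1 and 4.99 in irradiated 2. Without irradiated 2 the endothelial list still passed upward, at adjusted p = 0.00067 and a median of 0.64. The endothelial cadherin gene Cdh5 was at 9.58 and 134 CPM against 3.80 and 4.01 CPM, and Egfl7 at 4.34 and 67.9 CPM against 1.92 and 1.47 CPM. Of 23 fibroblast markers 15 lay above (adjusted p = 4.57e-05, and adjusted p = 0.767 with an estimated correlation), with medians of 0.14 and 2.55, and without irradiated 2 the adjusted p was 0.331. The collagen gene Col1a1 was at 261 CPM in irradiated 1 and 1766 CPM in irradiated 2 against 174 and 183 CPM, and Col6a3 at 31.5 and 153 CPM against 17.4 and 19.5 CPM. Of 11 pericyte markers 3 lay above (adjusted p = 0.0572), with medians of -0.19 and 1.45, Des at 3.58 and 8.69 CPM against 1.68 and 1.18 CPM and Ndufa4l2 at 1.66 and 3.94 CPM against 1.30 and 0.826 CPM. Without irradiated 1 the pericyte list passed, at adjusted p = 1.27e-05. None of the endothelial, fibroblast or pericyte markers passed when adjusted over the list alone.

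Markers of muscle, fat and red cells were scarce. Of 8 skeletal muscle markers 3 lay above (adjusted p = 0.0187, and adjusted p = 0.704 with an estimated correlation), with Neb at 1.66 and 1.87 CPM against 0.337 and 0.118 CPM and Atp2a1 at 2.57 and 1.87 CPM against 1.20 and 0.767 CPM, and without irradiated 2 the adjusted p was 0.655. Of 8 adipocyte markers 3 lay above and 2 below (adjusted p = 0.535), with Cfd at 0.656 and 3.89 CPM against 0.0962 and 0.177 CPM and Car3 at 0.555 and 6.88 CPM against 0.144 and 0.236 CPM. The erythroid list kept 4 tested members, too few for the list test, and 2 of them lay above. Hba-a1 was at 2.57 and 15.03 CPM against 0.529 and 1.42 CPM and Hbb-bs at 1.97 and 13.4 CPM against 0.192 and 0.944 CPM, both with near-identical copies. In these 3 lists 0 members passed when adjusted over the list alone.

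**Figure D2:**
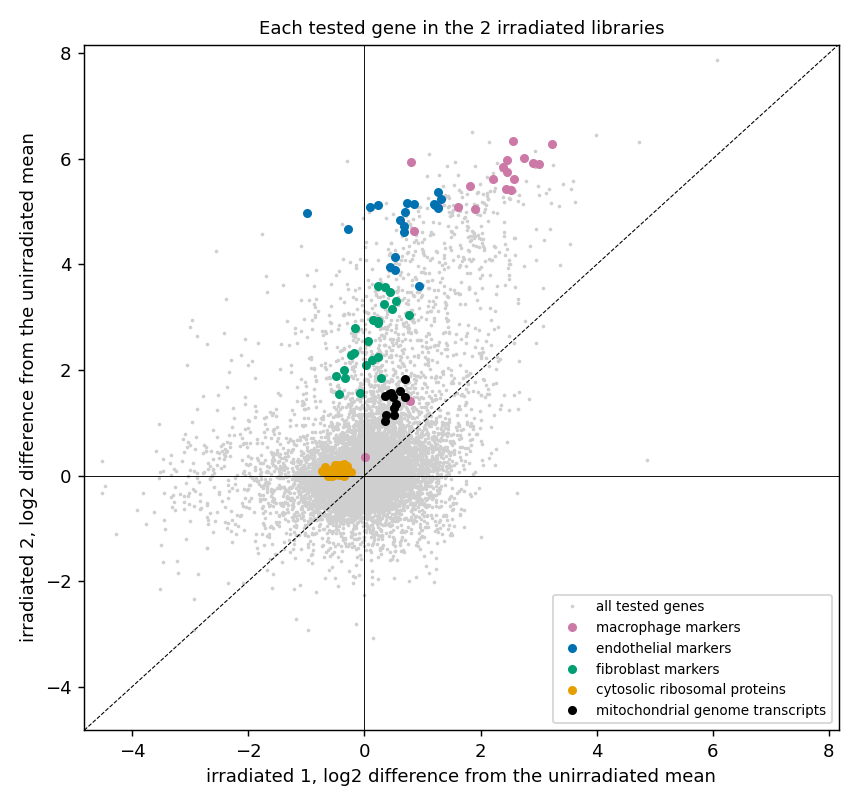
Log2 difference of each of the 15993 tested genes from the mean of the unirradiated libraries, in irradiated 1 (x axis) and irradiated 2 (y axis), with 5 gene lists in color and a dashed line of equal values. Macrophage markers lay at a median of 2.42 in irradiated 1 and 5.62 in irradiated 2, fibroblast markers at 0.14 and 2.55, and ribosomal protein genes at -0.45 and 0.11.

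Mitochondrial genome transcripts were higher in both irradiated libraries. All 13 lay above both unirradiated libraries in both irradiated ones, 10 passed when adjusted over the list alone, and the list passed at adjusted p = 4.96e-07 (adjusted p = 0.689 with an estimated correlation), with medians of 0.50 in irradiated 1 and 1.49 in irradiated 2, again the library with high markers of other cell types. mt-Atp6 was at 50.7 and 87.8 CPM against 33.2 and 29.1 CPM, and mt-Co2 at 39.8 and 87.5 CPM against 24.5 and 24.4 CPM. Both held only a small part of the counts of the mitochondrial genome, given next. The counting options are not given, so it is not known how reads that fit several places in the genome were counted. These values may therefore be too low. The mitochondrial genome held 1.71% (95% Wilson interval 1.70 to 1.71) and 1.64% (1.64 to 1.65) of the counts in the unirradiated libraries, 2.43% (2.42 to 2.44) in irradiated 1 and 3.72% (3.71 to 3.73) in irradiated 2, intervals that cover counting error only. Nuclear genes of oxidative phosphorylation did not follow: of 30, 0 lay above and 0 below (adjusted p = 0.258), with Sdhc at 69.4 and 83.4 CPM against 95.2 and 79.9 CPM and Ndufa4 at 72.8 and 111 CPM against 114 and 103 CPM. Without irradiated 2 that list passed downward (adjusted p = 0.000641), and without unirradiated 2 as well (0.0157).

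Ribosomal protein genes divided the irradiated libraries. The 30 genes had a median log2 difference of -0.45 in irradiated 1 and 0.11 in irradiated 2, so that 0 lay above or below in both, while the list passed downward at adjusted p = 0.0137 (adjusted p = 0.799 with an estimated correlation). The call was lost without irradiated 1 (adjusted p = 0.369, median 0.09) or unirradiated 1 (0.217). Rps18 was at 496 and 761 CPM against 812 and 725 CPM, and Rpl10 at 685 and 998 CPM against 1072 and 945 CPM. Irradiated 1 also had the fewest genes with a count, 20149 against 23939 in irradiated 2. The unirradiated libraries had 23070 and 22344. Whether the ribosomal values are tied to this was not tested.

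Of the hypoxia, protein stress, antioxidant and cholesterol lists only the first passed. Of 30 hypoxia and glycolysis genes 12 lay above and 5 below, and 3 passed when adjusted over the list alone (adjusted p = 0.0384, and adjusted p = 0.681 with an estimated correlation). The collagen hydroxylase genes P4ha1 and P4ha2 were at 39.1 and 44.1 CPM against 26.5 and 25.5 CPM and at 32.7 and 27.6 CPM against 15.6 and 16.8 CPM. Vegfa was at 452 CPM in irradiated 1 and 216 CPM in irradiated 2 against 229 and 233 CPM. The hypoxia call was lost without unirradiated 1 (adjusted p = 0.193), unirradiated 2 (0.265) or irradiated 1 (0.943). Of 25 genes of the unfolded protein and integrated stress response 1 lay above and 9 below (adjusted p = 0.0963, and 0.0486 without unirradiated 2), with the secretory regulator Xbp1 at 785 and 840 CPM against 1099 and 1067 CPM and Sel1l at 147 and 127 CPM against 155 and 166 CPM. Of 22 antioxidant genes 7 lay above and 5 below (adjusted p = 0.51), with Hmox1 at 125 and 116 CPM against 85.4 and 91.1 CPM and the cystine transporter gene Slc7a11 at 1.16 and 3.20 CPM against 0.241 and 0.531 CPM. Of 20 cholesterol synthesis genes 2 lay above and 6 below (adjusted p = 0.0879), with Dhcr7 at 53.7 and 58.6 CPM against 77.7 and 74.0 CPM and Sc5d at 45.1 and 50.4 CPM against 59.1 and 56.0 CPM. In the last 3 lists 0 members passed when adjusted over the list alone.

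Apoptosis genes and immediate early genes did not pass as lists. Of 19 pro-apoptotic genes 4 lay above and 5 below (adjusted p = 0.858), with Casp8 at 30.0 and 41.5 CPM against 24.3 and 25.2 CPM beside Pmaip1. Of 13 anti-apoptotic genes 2 lay above and 3 below (adjusted p = 0.65), with Bcl2 at 56.1 and 54.6 CPM against 65.8 and 68.7 CPM and Birc2 at 52.2 and 46.6 CPM against 53.9 and 58.6 CPM. Of 26 immediate early and dissociation genes 3 lay above and 4 below (adjusted p = 0.556), with a median of -0.0563, a mean of 0.00391 and a downward test direction. Klf2 was at 381 and 347 CPM against 278 and 263 CPM, Klf4 at 1092 and 723 CPM against 644 and 626 CPM, and Fos, among the most abundant transcripts of every library, at 12942 and 10551 CPM against 12788 and 12209 CPM. The immediate early medians were 0.14 in irradiated 1 and -0.25 in irradiated 2; without irradiated 1 the list passed downward (adjusted p = 0.000581), and without irradiated 2 it pointed up without passing (0.0691). In these 3 lists 0 members passed when adjusted over the list alone.

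**Figure D3:**
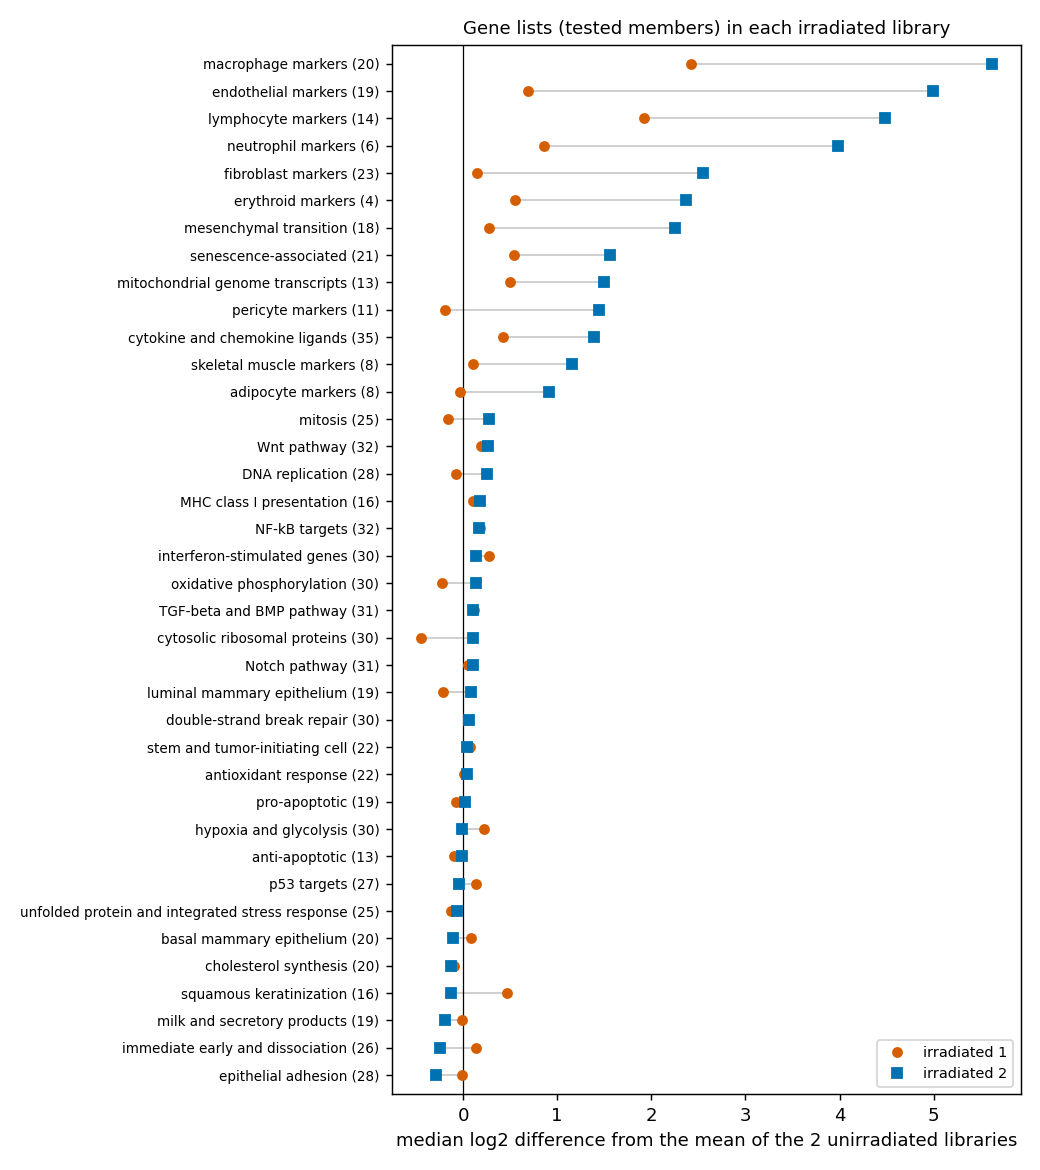
Median log2 difference from the mean of the unirradiated libraries for each of the 38 gene lists, in irradiated 1 (circles) and irradiated 2 (squares), with the number of tested members in brackets. Macrophage markers had the largest medians, 2.42 and 5.62, and 9 of the lists of other cell types lay higher in irradiated 2 than in irradiated 1.

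Each irradiated library was also set against the unirradiated pair alone. Of 16301 genes tested in both fits, irradiated 1 had 1866 genes higher and 2347 lower and irradiated 2 had 2249 higher and 1354 lower. Both had 658 genes higher, where independent lists would share 257, and 358 lower, where they would share 195; 222 genes were called in opposite directions. In 20 simulations of unchanged libraries with the spread of the unirradiated pair each fit called at most 0.05 genes on average, so their overlap of 0 gives no chance value for the shared calls. With unchanged irradiated libraries drawn at the spread of the irradiated pair, a simulation added after the result was seen, 838 genes were higher in both (688 for independent lists), 846 lower in both (703) and 1483 opposite on average. Those simulated lists were longer than the observed ones, so the raw counts, those of opposite calls among them, cannot be set against each other. Relative to independent lists, the observed overlaps lay further above than the simulated ones. How far an overlap can rise above independent lists also depends on list length, so no excess over chance can be read from this. The simulated spread of the irradiated pair includes any real difference between the irradiated libraries. The log2 fold changes correlated at 0.363 across genes, against 0.353 in the first simulations and 0.105 in the second, and their covariance was 0.377 against 0.0411 and 0.0598. With each irradiated library set against a different unirradiated one, also added after the result was seen, the log2 differences of 15993 genes had a covariance of 0.205 (irradiated 1 with unirradiated 1) and 0.239 (irradiated 1 with unirradiated 2), and correlations of 0.30 and 0.361. Such a comparison holds 1 control each and makes no calls. It used differences of log2 CPM, with a prior count of 2, over another set of genes than the fits. Its covariances can therefore not be set directly against 0.377. Part of the shared calls may come from the shared controls. Of the 658 genes, 287 were over 2-fold further up in irradiated 2 and 3 in irradiated 1. Called higher in both fits were 16 of 20 macrophage markers, 10 of 13 mitochondrial genome transcripts and 8 of 30 interferon-stimulated genes, and of 19 milk and secretory genes 3 were called higher and 7 lower in both. The ribosomal protein genes had 29 of 30 called lower in irradiated 1 and 0 in irradiated 2.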

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

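The robust quasi-likelihood fit was chosen after the result was seen; the other settings were planned. limma-voom called 0 genes in either direction, as did edgeR under DESeq2 size factors, upper-quartile scaling, library size alone, the stricter filter, the robust fit, an adjusted p under 0.1 and an added fold threshold. Without a low-count filter edgeR called 1338 genes higher and 105 lower (27538 genes tested), with infinite prior degrees of freedom against 3.00; the cause was not tested. DESeq2 called 450 and 50; 301 of its 417 higher calls among genes tested by edgeR were over 2-fold higher in irradiated 2 than in irradiated 1. Leaving out a library gave 0 to 2713 genes higher and 0 to 2355 lower; the calls came without irradiated 1 or irradiated 2, where the spread is that of the unirradiated pair. The coefficient of variation, 28.0% with all libraries, ranged from 5.94% without irradiated 2 to 46.0% without unirradiated 2. The replicate block called 2 genes higher and 0 lower. Same-numbered libraries deviated from their group means with a correlation of -0.0992 across genes. The labels do not say what the number marks. With the wide spread of the irradiated pair, this correlation cannot tell whether same-numbered libraries share more than it.

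Of 18 lists past the threshold, 0 remained with an estimated correlation and 1 with fry; leaving out a library gave 11 to 18 (11 without irradiated 2, 12 without unirradiated 1, 10 and 12 of them among the 18). The replicate block gave 16, of which 15 were among the 18. The median of the ribosomal protein list ranged from -0.467 without irradiated 2 to 0.0915 without irradiated 1. Over libraries left out, log2 fold changes ranged from -0.71 to 0.16 for Dll1, -0.14 to 0.41 for Mdm2 and -0.591 to 0.0154 for Ndufa4.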

Other observations

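The tests in this part were chosen after the result was seen; only for the matched-list test of ribosomal protein genes was the outcome sought written down before it was run. Salivary-type secretory transcripts, a list put together after the values were seen, lay on both sides: of 16 tested genes 7 lay above both unirradiated libraries in both irradiated ones and 7 below, and 0 passed edgeR over all genes. Bpifa2, a secreted protein of salivary glands, was at 3.75 and 6.37 CPM without radiation, 61.5 CPM in irradiated 1 and 182 CPM in irradiated 2, Dcpp1 at 8.71 and 7.96 CPM, 67.5 CPM and 335 CPM, and the amylase gene Amy1 at 3.18 and 3.60 CPM, 23.4 CPM and 54.5 CPM. Car6, the secreted carbonic anhydrase gene, went the other way, from 112 and 91.0 CPM to 19.1 and 54.8 CPM, as did the secretoglobin gene Scgb2b27, from 387 and 335 CPM to 72.9 and 174 CPM, and the water channel gene Aqp5, from 654 and 623 CPM to 420 and 455 CPM. Chia1, given above for its small p, is on this list and lay above with Bpifa2, Dcpp1 and Amy1. Dcpp1, Amy1 and the secretoglobins have near-identical copies, so their values are uncertain. A test for salivary tissue as the source was run and then left out, because Car6 and Scgb2b27 were already high without radiation, so its outcome could not tell.

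MHC class II genes, carried by antigen-presenting cells, were higher as well: 7 of 9 lay above both unirradiated libraries, with a median log2 difference of 1.63 in irradiated 1 and 4.28 in irradiated 2, where markers of other cell types were high. The invariant chain gene Cd74 was at 21.4 and 13.0 CPM without radiation, 66.3 CPM in irradiated 1 and 773 CPM in irradiated 2. Immunoglobulin genes together were at 8.84 CPM (95% Wilson interval 7.65 to 10.2, counting error only) and 8.80 CPM (7.495 to 10.3), against 40.3 CPM (37.7 to 43.2) and 242 CPM (235 to 249). Of 14 hormone and growth factor receptor genes 1 lay above, Igf1r, at 14.1 and 16.7 CPM against 8.08 and 10.4 CPM, and 4 below, among them Egfr, at 80.6 and 72.4 CPM against 103 and 101 CPM, and none passed when adjusted over the list alone. The estrogen receptor gene Esr1 was at 6.86 and 9.06 CPM against 7.17 and 8.32 CPM.

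The markers of other cell types in irradiated 2 were not limited to mesenchymal genes. A mesenchymal shift of the tumor cells without other cells would leave endothelial and blood cell markers low. The 59 such markers had a median log2 difference of 5.04 (quartiles 4.32 and 5.37). They come from the same lists that showed the pattern, so this value restates it and is no separate test of that shift. Other cells in that library may account for part of the pattern, as a hypothesis. Of 22 further abundant transcripts of such cells, 20 were above 1 CPM in both controls. The 18 on no fixed list had a median of 2.16 (quartiles 0.908 and 3.91). Values of these transcripts had been seen before this median was chosen as the test, so it is no independent evidence. Sorting on CD45, CD31 and TER119 would remove the blood and endothelial cells. Of the 22, 20 lay above both controls in irradiated 2, by unequal amounts: Apoe was at 817 CPM against 127 and 119 CPM, while Ctsd, not above them, was at 380 CPM against 406 and 386 CPM, Ctsb at 889 CPM against 807 and 759 CPM, Psap at 1503 CPM against 1343 and 1284 CPM and Grn at 274 CPM against 221 and 215 CPM. Whether radiation brought such cells cannot be told apart from the sort of that tumor, since in irradiated 1 the median was above 1 in 2 of the 6 lists only.

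The low ribosomal protein transcripts of irradiated 1 were set against a loss of short and abundant transcripts. In 10000 random lists of genes near the ribosomal ones in length and expression the middle median was -0.0574. The lowest was -0.26, and 0 reached the ribosomal median of -0.45. The length used was that given per gene, not that of the transcripts present, so the test cannot decide whether short transcripts were lost. The match was also incomplete, with a median length of 2085 bases against 1730 bases. The average log2 CPM was 9.07 against 9.525, and the lists were drawn from 279 genes. Nuclear genes of oxidative phosphorylation differed in the same directions, with medians of -0.22 in irradiated 1 and 0.13 in irradiated 2. Whether radiation contributed cannot be told apart from other differences between the 2 irradiated libraries, since the median in irradiated 2 was 0.11.

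The 4 libraries can be split 2 against 2 in 3 ways, too few for a share under 0.05. The real split held 1480 genes at an unadjusted p under 0.05 and the highest other split 379. So 1 of the 3 splits, the real one itself, held as many. Every other split parts the unirradiated libraries, which lay close together, and so widens the spread within groups. The real split could therefore come first without any effect of radiation.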
